A study of Mus musculus with 4 samples.

How the data were processed

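Whole liver RNA of fasted male mice was hybridized to 4 whole-genome expression arrays, 1 per group: natural aging, aging diabetic, aging diabetic with metformin, and aging diabetic with astragalus polysaccharide (APS) and metformin. Per the file headers, all 4 arrays lay on 1 slide and were read in 1 scan and 1 channel, the red channel (Cy5), so slide and scan do not separate the groups. The deposited array files hold spot intensity that Agilent Feature Extraction had background-subtracted and detrended within each array; the file headers give version 11.5.1.1 and the labels version 10.7. Per the file headers, the other columns used are an error of the processed signal and flags of 0 or 1 for spots well above background, saturated spots and outlier spots. The deposited series table holds log2 values from the authors' array software after a normalization whose method is not stated. Its columns have equal quartiles (medians of 7.84), and each correlates with its own array at 0.9999 or more, against 0.958 at most with another array. These log2 values differed from a quantile normalization of the deposited intensities by an SD of at most 0.005.

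The log2 of the processed signal was taken and each array's 75th percentile subtracted, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The log2 values of the spots of the 300 probes that are spotted 10 times were averaged. Spots with an outlier flag were left out; of 56605 probes, 4825 had no other spot on at least 1 array and were dropped, and 51780 remained. Transcript accessions came from the array files and were matched, without their version, to a table of mouse transcripts that gave the gene symbols. By this, 33767 probes matched 23462 symbols and 22838 probes matched none. Unmatched probes are not counted among the other probes of a gene. Coordinates were not used. Leaving out outlier spots left 22047 genes with a usable probe and 1415 without, among them 141 genes of the lists and the fixed set. For the 6702 genes with several usable probes, the probe with the highest mean signal over the 4 arrays stood for the gene.

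A gene was compared where at least 1 of the 2 arrays was well above background. It was counted as higher or lower at a log2 difference of 1 or more in size. Where only 1 array was well above background, the difference was taken as a bound against the higher of the dim signal and the lowest signal well above background on that array (log2 -4.52 on the natural aging, -4.76 on the aging diabetic, -4.95 on the metformin and -4.84 on the APS plus metformin array). With 1 array per group there are no residual degrees of freedom, so no test was run. The error of a difference combines the errors that Feature Extraction gives for both spots, and covers measurement only. The 75th percentile of the signal was 2699.5 on the natural aging, 3068 on the aging diabetic, 3589 on the metformin and 3406 on the APS plus metformin array.

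The comparisons were aging diabetic against natural aging, metformin against aging diabetic, APS plus metformin against aging diabetic, and APS plus metformin against metformin. Both treated groups were also compared with natural aging. The 43 gene lists, the comparisons, the threshold and the alternatives below were set before the data were examined, except where stated. For each list the median log2 difference of its detected members, bounds included, was set beside 10000 random lists of the same size, drawn within 20 strata of mean signal. A list is said to stand apart below percentile 2.5 or above 97.5, and lists share genes, so they are not independent. The random lists hold unrelated genes, so they give no chance level for lists whose members vary together. The share of genes turned back, the correlations and the overlaps were set beside 100 shuffles of the 4 arrays within each gene, which give the level that a shared array produces when arrays are exchangeable.

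Named genes follow a rule set in advance. It takes, per comparison, the 10 largest positive and the 10 largest negative differences among genes well above background on both arrays, the 3 largest bounds per direction, up to 4 members with the largest difference from each list that stands apart, and 13 fixed genes. Genes of the ranking without a known function or official symbol were left out of the text, and some genes that the rule names are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

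The procedure was tested on simulated data with the signals and errors of these arrays, with 100 genes changed at each size. At 1.5 log2 it recovered 99.0% in aging diabetic against natural aging, 100.0% in metformin against aging diabetic, 100.0% in APS plus metformin against aging diabetic and 99.0% in APS plus metformin against metformin. At 3.0 log2 it recovered 100.0% in each of these comparisons. In the same order it called 1, 2, 3 and 4 unchanged genes, out of 12678 to 13670. A planted list came out at percentile 100.0 each time, and 2.5%, 7.5%, 7.5% and 2.5% of lists without a planted difference stood apart. The simulation holds measurement noise and no variation between animals. It was run only on genes well above background on both arrays, so the rule for bounds was not tested. Its lists were drawn from unrelated genes with measurement noise alone, so the planted list says little about lists in the real data.

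There were 8 alternatives set in advance: quantile normalization and cyclic loess between arrays (R 4.3.3, limma 3.58.1), centring on the median of the probes well above background on all 4 arrays, normexp background correction with an offset of 50, the authors' series values, the mean of all detected probes of a gene, only genes detected on all 4 arrays, and no detection filter. The normexp correction used the median spot signal, since the files hold no mean spot signal. A further alternative, keeping outlier spots, was added after the data had been seen. All 56605 probes of the arrays were found in the series table, which has 56743 rows.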

Results

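Liver RNA from male mice was measured in 4 groups with 1 array each: naturally aging mice, aging diabetic mice, aging diabetic mice given metformin, a biguanide that lowers blood glucose, and aging diabetic mice given metformin together with astragalus polysaccharide (APS), a polysaccharide preparation from the root of a medicinal plant. The series asks how the combination relates to the liver mRNA profile of aging diabetic mice. There were no replicates, so no test across animals was possible, and every difference here is a difference between 2 arrays. The labels do not say whether each RNA came from 1 mouse or from a pool, and the meaning of the 60 days in the sample titles is not stated. "Higher" and "lower" therefore describe these arrays only.

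Each array held 59305 spots that were not controls. Of these, 33668 were well above background on the natural aging array, 34895 on the aging diabetic array, 37402 on the metformin array and 35743 on the APS plus metformin array. The median local background was between 44 and 47 on all 4 arrays, and no spot was saturated. Probes spotted 10 times had a median SD between 0.058 and 0.070 log2 within an array, and the median error that the image analysis gave for a difference was 0.165 log2 for the aging diabetic against the natural aging array. Neither figure holds the spread between animals. A gene was counted as higher or lower at a difference of 1 log2 (2-fold). Other probes of the counted genes had the same sign for 88.8% of 509 probes in the aging diabetic against natural aging comparison, and were themselves past 2-fold the same way for 46.4%; between the diabetic groups these shares were 86.6% to 89.9% and 47.1% to 49.6%, and for the treated arrays against natural aging 86.1% to 86.4% and 43.7% to 43.8%. Where only 1 of both arrays was well above background, the difference is given as at least N-fold, against the lowest signal well above background on the dimmer array or the probe's own signal, whichever was higher.

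In the aging diabetic array, most detected genes of the female-biased and fetal liver lists were higher than in natural aging. The list of genes with a male-biased pattern in mouse liver had a negative median, with 6 of 14 members lower and 1 higher. Genes of the exocrine pancreas were much lower. Lists for the cell cycle, lymphocytes, matrix, cytokines and cholesterol synthesis had medians below 0, with most members of each short of 2-fold. Of 14453 genes compared, 1185 were at least 2-fold higher and 880 at least 2-fold lower. The 43 lists were set before the data were examined, and 24 of them stood apart from random lists of the same size and brightness. If members of a list varied independently, 2.15 would be expected. Members may vary together between any pair of arrays, which random lists do not hold, so the number expected by chance is not known. Across all pairs of arrays, 17 to 26 lists stood apart. The comparison of aging diabetic with natural aging bears on how the diabetic state differs from aging alone.

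The female-biased list had a median of 1.28 log2 (0.83 without members that give only a bound), with 9 of 17 detected members at least 2-fold higher and 1 lower. Cyp17a1, a steroid hydroxylase, was 38.3-fold higher with an error of 0.213 log2, and the fatty acid hydroxylase gene Cyp4a14 was 26.8-fold higher. Slc22a27, an organic anion transporter, was 14.6-fold higher, and Cux2, a transcription factor of female liver, was 5.96-fold higher. The male-biased list had a median of -0.85, with 6 of 14 members at least 2-fold lower. The organic anion transporter gene Slco1a1 was 29.3-fold lower, Elovl3, a fatty acid elongase, was 9.15-fold lower, and Egfr was 3.79-fold lower. Hsd3b5, a steroid dehydrogenase of male liver, was at least 178-fold lower, while Susd4 went the other way and was 3.69-fold higher.

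Pancreatic acinar genes had the largest median in size of the 43 lists in this comparison, with a median of -4.10 log2 and 14 of 15 members lower. The amylase gene Amy2b was 105-fold lower, and the carboxypeptidase genes Cpa1 and Cpb1 were 33.0-fold and 31.7-fold lower. Cel, which encodes a bile salt-dependent lipase, was 33.1-fold lower and the elastase gene Cela3a was 26.2-fold lower. These genes were bright on the natural aging array, where Cpa1 stood at 2.79 log2 above the array's 75th percentile, against -2.25 on the aging diabetic array.

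Oncofetal genes had a median of 1.05, with 7 of 13 members at least 2-fold higher and 2 lower. The imprinted RNA H19 was 26.4-fold higher, alpha-fetoprotein (Afp) was 3.69-fold higher, and Akr1c18, a steroid reductase, was 4.47-fold higher. Outside the lists of sex and fetal genes, Hamp, which encodes the iron hormone hepcidin, was 20.4-fold higher, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 12.0-fold higher. Phlda3 was 34.1-fold higher and the brush border cadherin gene Cdhr2 was 19.3-fold higher. Mogat1, which makes diacylglycerol, was 10.9-fold higher although the lipid synthesis list it belongs to had a median of -0.38 (-0.25 after quantile normalization) and stood below its random lists.

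Cell cycle genes had a median of -0.70 (-0.27 without bounds), with 9 of 24 lower and none higher. The replication helicase genes Mcm6 and Mcm5 were 14.8-fold and 4.57-fold lower, and the proliferation marker Mki67 was 6.10-fold lower. Lymphocyte markers had a median of -0.86, with the granzyme gene Gzma 5.81-fold lower and the natural killer cell gene Nkg7 4.56-fold lower. The matrix and stellate cell list had a median of -0.66, with Pdgfrb 4.68-fold lower and the collagen gene Col3a1 3.76-fold lower. The median of the cytokine list was -0.71, where the neutrophil attractant Cxcl1 was 9.52-fold lower and Ccl3 was 3.88-fold higher. Immediate-early genes, which respond within minutes to stress or handling, had a median of -1.03, with Egr1 12.3-fold lower and Atf3 4.70-fold lower. Medians were also low for neutrophil (-0.56), erythroid (-0.51), macrophage (-0.50, or -0.32 after cyclic loess), endothelial (-0.41), and antigen presentation (-0.64) lists. The acute-phase list stood at -0.44 against -0.27 for random lists as bright, and at -0.12 after quantile normalization.

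Cholesterol synthesis had a median of -0.45 (-0.28 after cyclic loess), with squalene epoxidase (Sqle) at -0.96, while Mvd, of the mevalonate pathway, was 2.22-fold higher. Glycolysis and glucose uptake had a median of -0.36 against -0.22 for random lists as bright (-0.08 after quantile normalization), with Pfkfb3, a regulator of glycolytic flux, 6.07-fold lower; this list was back within its random lists after cyclic loess (percentile 3.59). Differences were -0.45 for G6pc and -0.31 for Pck1, both of gluconeogenesis, and -0.995 for the lipogenic regulator Srebf1. They were -1.05 for the insulin receptor substrate Irs2, -0.86 for Igfbp1, -0.08 for Cpt1a and -0.15 for Ppargc1a. The gluconeogenesis list had a median of -0.20 (0.04 after quantile normalization), against -0.26 for random lists as bright. Differences of single genes, here and below, were not adjusted for such a shift of bright genes. Fasn and Scd1 had an outlier spot on at least 1 array and were left out. With those spots kept, Fasn differed by -0.61 and Scd1 by -0.80.

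Random lists as bright as the oxidative phosphorylation list had a median of -0.27 on the aging diabetic array, so medians are read against lists of the same brightness. Oxidative phosphorylation (median -0.19, percentile 99.2), fatty acid oxidation and PPAR-alpha targets (median -0.05, mean 0.20, percentile 99.7) and amino acid catabolism (within 0.01 of 0) stood above their random lists. These medians were at or under 0, and after quantile normalization they were 0.11, 0.22 and 0.27. Of the 37 genes listed for fatty acid oxidation and PPAR-alpha targets, only 27 had a usable probe, with 4 at least 2-fold higher and 1 lower. The interferon list (median 0.20) was back within its random lists after quantile normalization (percentile 96.4) and in the authors' series values (95.3), as was the heat shock list (median -0.34 against -0.06 after quantile normalization). Ribosomal proteins (median -0.37, or -0.04 after quantile normalization) were within theirs when probes were averaged (percentile 2.93) and with outlier spots kept (3.92). Tob2 was at least 179-fold lower by a single probe that was dim on the aging diabetic array alone, and has no other probe to check it.

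**Figure D1:**
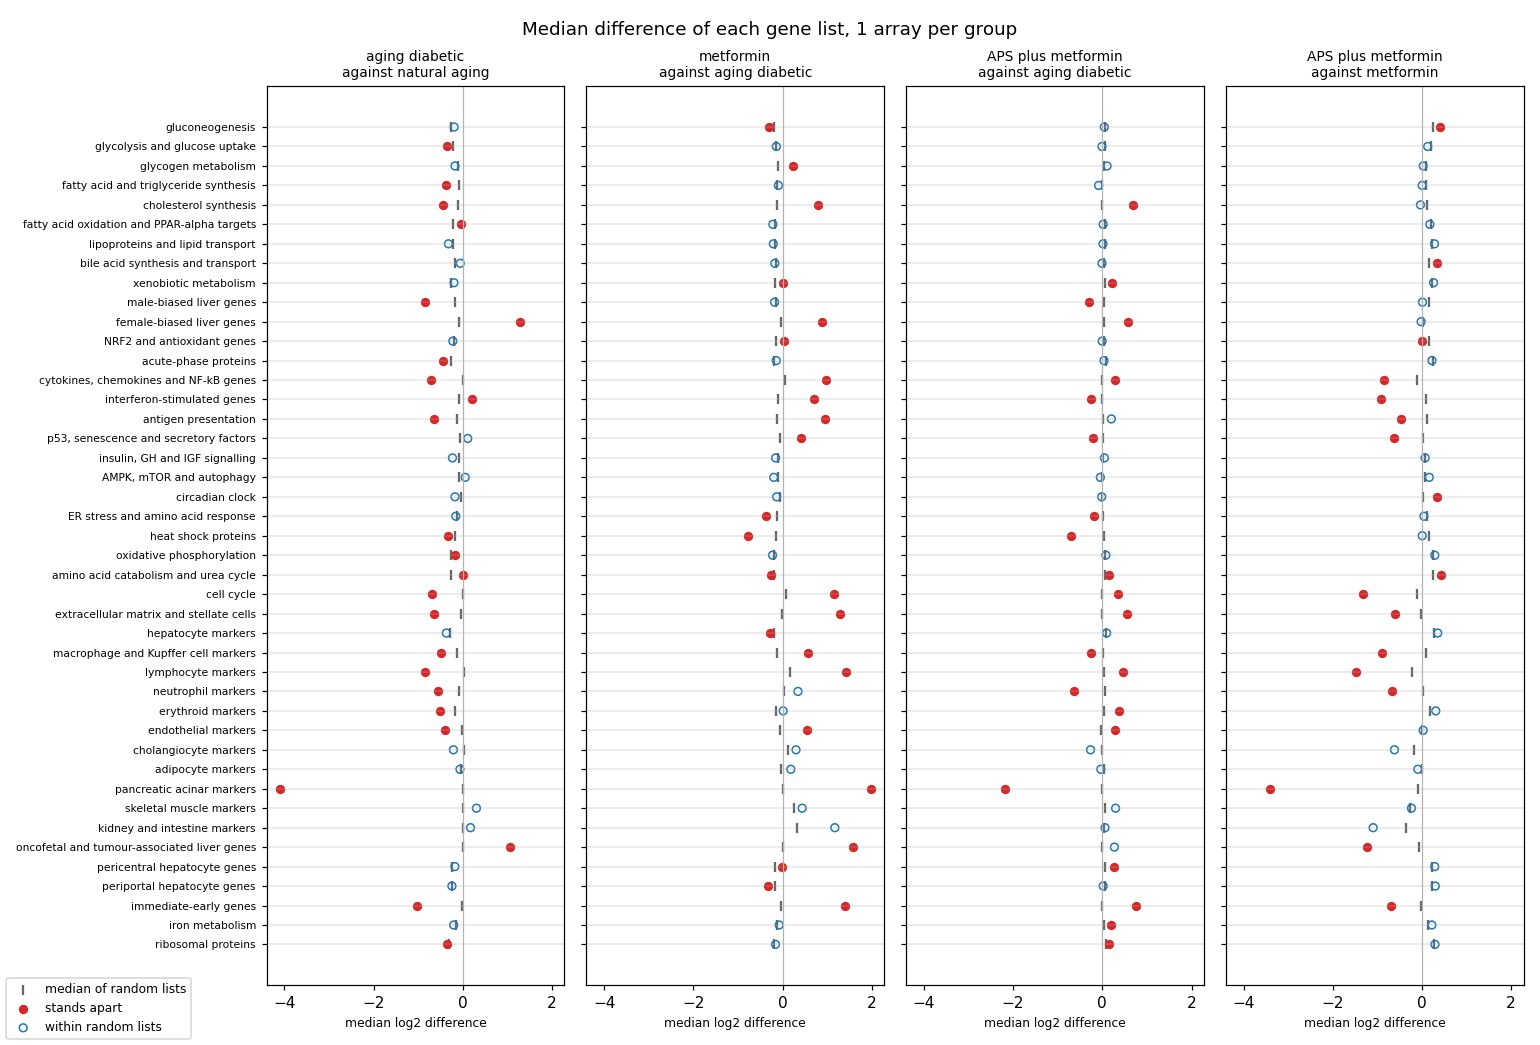
Median log2 difference (x axis) of the detected members of each of 43 gene lists (y axis) in the 4 comparisons, with 1 array per group. Filled points lie outside the central 95% of 10000 random lists matched on brightness, open points lie within, and vertical ticks mark the median of the random lists; the pancreatic acinar list lies at -4.10 in aging diabetic against natural aging.

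Against the aging diabetic array, the metformin array had positive medians for the cell cycle, lymphocyte, matrix, fetal liver, cytokine, interferon and cholesterol synthesis lists. Most members of the cell cycle, lymphocyte, matrix and fetal liver lists were at least 2-fold higher. Most members of the other lists named were short of 2-fold. The heat shock median was negative, with 5 of 14 members lower, and hepatocyte markers stood slightly below lists of like brightness. Meg3, Dlk1, Rian and Igf2 were among the genes over 10-fold higher. Of 15562 genes compared, 1851 were at least 2-fold higher and 549 at least 2-fold lower, and 24 of the 43 lists stood apart. The comparison bears on what metformin alone goes with in diabetic liver.

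Cell cycle genes had a median of 1.15 log2 (0.77 without bounds), with 14 of 24 higher and none lower. Mcm6 was 32.6-fold higher, the cyclin gene Ccnb1 was 9.05-fold higher and Mki67 was 8.12-fold higher. Lymphocyte markers had a median of 1.42, with Nkg7 16.2-fold, Gzma 12.1-fold and the T cell receptor component Cd3g 8.80-fold higher. In the matrix and stellate cell list (median 1.28), 14 of 21 members were higher, among them Pdgfrb at 5.76-fold and Col3a1 at 4.74-fold. The macrophage list had a median of 0.57 and went both ways. Cx3cr1 and Ccr2, receptors of recruited monocytes, were 12.3-fold and 6.32-fold higher, and Cd163, a scavenger receptor of resident macrophages, was 3.60-fold lower. Endothelial markers had a median of 0.54, and hepatocyte markers had a median of -0.29 against -0.19 for random lists as bright (-0.10 after quantile normalization), with Alb at -0.33.

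Cytokine and chemokine genes had a median of 0.98, with the monocyte attractant Ccl2 15.1-fold and Ccl5 10.2-fold higher. Interferon-stimulated genes had a median of 0.71, with 10 of 25 higher, among them Ifit2 at 5.06-fold and Ifi44 at 3.38-fold. Antigen presentation had a median of 0.96, with the class II gene H2-Eb1 2.62-fold higher. The list of p53 targets, senescence and secreted factors had a median of 0.41, with 6 of 26 members higher and 1 lower. Immediate-early genes had a median of 1.39, with Egr1 7.35-fold and Fos 4.72-fold higher.

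Oncofetal genes had a median of 1.59, with 9 of 13 higher. Igf2, a fetal growth factor, was 12.1-fold higher, the glypican gene Gpc3 was 6.13-fold higher, and Akr1c18 was 8.68-fold higher. The imprinted RNAs Meg3 and Rian were 44.6-fold and 13.2-fold higher, and Dlk1, from the same imprinted region, was 27.4-fold higher. The female-biased list again had a positive median of 0.88 (0.54 without bounds), with 9 of 19 members at least 2-fold higher and 2 lower. The oxidase gene Hao2 was 17.6-fold and Sult2a2 8.86-fold higher. The sulfotransferase gene Sult3a1 was at least 60.2-fold higher. Pancreatic acinar genes had a median of 1.97, with 12 of 15 members higher.

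Cholesterol synthesis had a median of 0.79, with Sqle 6.50-fold and Cyp51 3.76-fold higher. Heat shock genes had a median of -0.78, with Hspa1a 8.11-fold, Hspa1b 6.69-fold and Hsph1 7.24-fold lower; Hspa1a and Hspa1b are near-identical copies that were not told apart here. The endoplasmic reticulum list had a median of -0.38 (-0.24 after cyclic loess), where the chaperone gene Sdf2l1 was 3.13-fold lower and asparagine synthetase (Asns) was 6.49-fold higher. Derl3, which acts in the export of misfolded proteins, was 20.8-fold lower. The leptin receptor gene Lepr was 20.4-fold lower, and its other probe differed by -3.79. Among the remaining genes fixed for every comparison, differences were -0.14 for G6pc, -0.39 for Pck1, 0.34 for Srebf1, -0.30 for Cpt1a and -0.72 for Cyp7a1. They were 0.40 for Ppargc1a, -0.50 for Irs2, -0.06 for Igfbp1 and 0.54 for Cyp4a14. Random lists as bright as the gluconeogenesis list had a median of -0.18 here. With outlier spots kept, Fasn differed by -0.27 and Scd1 by -0.18.

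The gluconeogenesis list had a median of -0.31 (-0.12 after quantile normalization) and stood below its random lists, but was within them after normexp background correction (percentile 9.42). Glycogen metabolism (median 0.23) turned to -0.13 without bounds and when all detected probes of a gene were averaged, where the list was within its random lists (percentile 40.6). Xenobiotic metabolism (within 0.01 of 0, against 0.15 after quantile normalization) and pericentral genes (median -0.02, against 0.15) stood above their random lists without a median clearly above 0, and the pericentral list was within them after normexp correction (percentile 95.1). The antioxidant list did so at 0.02, against 0.17 after quantile normalization and -0.02 over genes detected on all 4 arrays. Periportal genes (-0.32, or -0.17 after quantile normalization) and amino acid catabolism (-0.27, or -0.11) stood below theirs, which lay at -0.18 and -0.19.

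Relative to the aging diabetic array, the array of APS plus metformin had positive medians for the cholesterol synthesis, female-biased, immediate-early and matrix lists. Most members of each were short of 2-fold. Medians were negative for the pancreatic acinar, heat shock, neutrophil and male-biased lists. At least 2-fold lower were 12 of 14 acinar, 5 of 14 heat shock, 4 of 12 neutrophil and 5 of 13 male-biased members. In the neutrophil list 1 member was higher. Of 14734 genes compared, 646 were at least 2-fold higher and 1017 at least 2-fold lower, and 22 of the 43 lists stood apart. The comparison bears on what the combination goes with in diabetic liver.

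Cholesterol synthesis had a median of 0.69 log2, with Sqle 4.90-fold and Cyp51 2.95-fold higher. Female-biased genes had a median of 0.57, with 8 of 19 higher and none lower. The sulfotransferase genes Sult2a2 and Sult2a4 were 11.1-fold and 8.83-fold higher. Male-biased genes had a median of -0.30, with Susd4 6.30-fold and Cyp4a12a 2.43-fold lower. Xenobiotic metabolism had a median of 0.23 (0.10 after quantile normalization), with Cyp1b1 3.61-fold higher, and pericentral genes had a median of 0.25 (0.14), with Lgr5 at 0.97; the pericentral list was within its random lists after normexp correction (percentile 97.1). Glutathione transferase gene Mgst2 was 12.1-fold higher, Meg3 was 18.3-fold higher and Ppargc1a, a coactivator of fasting metabolism, was 3.23-fold higher.

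Heat shock genes had a median of -0.70, with Hspa1a 32.2-fold, Hspa1b 14.4-fold and Hsph1 9.70-fold lower. The endoplasmic reticulum list had a median of -0.19, with Creld2 4.46-fold, Sdf2l1 4.21-fold and the stress factor gene Ddit3 2.74-fold lower. Derl3 was 60.5-fold lower. Pancreatic acinar genes had a median of -2.19 (-1.18 without bounds), with the chymotrypsinogen gene Ctrb1 24.7-fold lower and the trypsinogen gene Prss2 at least 22.9-fold lower. Neutrophil markers had a median of -0.64 (-0.43 without bounds), with the antimicrobial peptide gene Camp 5.26-fold and Chil3 4.40-fold lower, while Il1b was 2.25-fold higher. Macrophage markers had a median of -0.26, with the scavenger receptor genes Marco and Cd163 5.09-fold and 3.40-fold lower. Interferon-stimulated genes had a median of -0.25, with the proteasome subunit gene Psmb9 2.67-fold lower.

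Immediate-early genes had a median of 0.74, with Myc 3.33-fold and Klf4 2.79-fold higher. The matrix and stellate cell list had a median of 0.56, with Pdgfrb 3.12-fold higher, and lymphocyte (0.46), erythroid (0.37), endothelial (0.29) and ribosomal protein (0.15, or 0.01 after quantile normalization) lists also stood above theirs. Iron metabolism had a median of 0.19 (0.11 after cyclic loess), with Id1 3.95-fold and Hamp 3.55-fold higher. Among the other fixed genes, differences were -0.11 for G6pc, 0.12 for Pck1, 0.30 for Srebf1, -0.01 for Cpt1a, 0.38 for Cyp7a1, 0.35 for Irs2, 0.46 for Igfbp1 and 0.38 for Cyp4a14. With outlier spots kept, Scd1, the stearoyl-CoA desaturase, differed by -3.42 and Fasn by -0.69.

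Several of these lists depended on a setting. The list of p53 targets and senescence factors (median -0.21) was within its random lists when probes were averaged (percentile 12.6) and over genes detected on all arrays (9.89). It was also within them without a detection filter (7.69) and, narrowly, after quantile normalization (2.70) and in the series values (2.53). The cell cycle list (median 0.36) was within its random lists with averaged probes (95.6) and without a detection filter (88.7). Iron metabolism was so after normexp correction (92.3), with averaged probes (94.2) and, narrowly, without a detection filter (97.48). Amino acid catabolism (median 0.14) was so after quantile normalization, at -0.01, and after normexp correction (97.0). The cytokine list (median 0.29) was so without a detection filter (91.8) and with outlier spots kept (94.2).

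**Figure D2:**
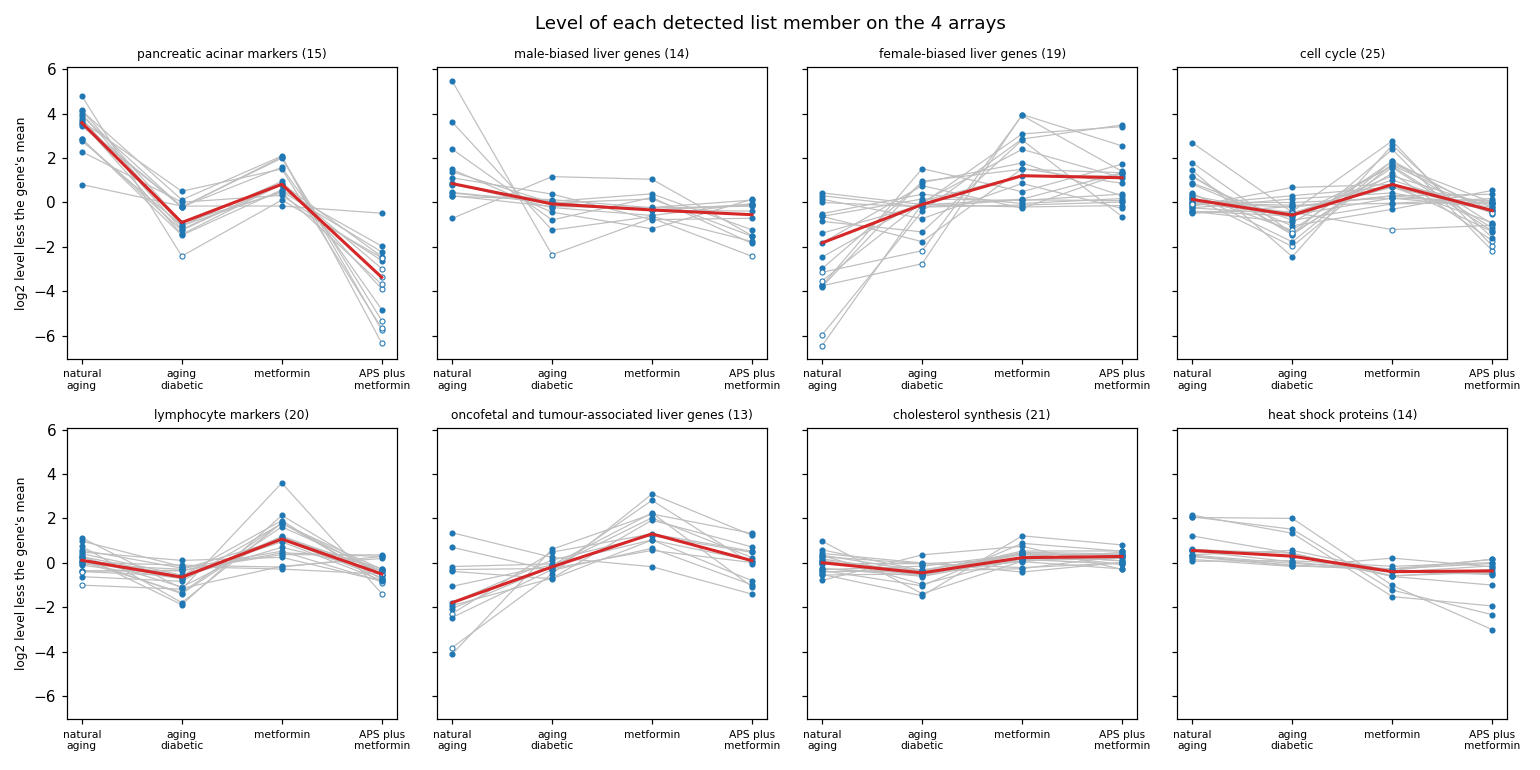
Level of each detected member of 8 lists, chosen for display after the values were seen, on the 4 arrays as log2 signal less the gene's own mean over the arrays (y axis). Open points are not well above background, grey lines join a gene and the red line joins the medians; the acinar median goes from 3.59 on the natural aging array to -3.37 on the APS plus metformin array.

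Against metformin alone, APS plus metformin had negative medians for the lymphocyte, cell cycle, fetal liver, interferon, macrophage, cytokine and pancreatic acinar lists. The circadian list had a median of 0.34 log2 (0.18 after cyclic loess). Gluconeogenesis, amino acid catabolism and bile acid lists stood above random lists as bright, which were themselves at 0.25, 0.25 and 0.16. Of 15599 genes compared, 370 were at least 2-fold higher and 1939 at least 2-fold lower, and 17 of the 43 lists stood apart. Cyclic loess moved the median of all genes in this comparison by -0.15 log2, the only alternative scaling to move a median of all genes by over 0.1. The comparison bears on what APS goes with when added to metformin.

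Lymphocyte markers had a median of -1.47 log2, with 15 of 20 lower and none higher, among them Nkg7 at 6.37-fold and Cd3g at 4.90-fold. Cell cycle genes had a median of -1.31, with Mcm6 18.0-fold, Mki67 7.23-fold and the survivin gene Birc5 6.88-fold lower. Macrophage markers had a median of -0.89 (-0.63 without bounds), with Ccr2 6.94-fold and Trem2 6.12-fold lower. In the cytokine list (median -0.84), Ccl2 was 9.64-fold and Ccl3 8.96-fold lower. Interferon-stimulated genes had a median of -0.91, with Oasl2 6.62-fold and Ifi44 5.82-fold lower. Antigen presentation had a median of -0.47, and the class II activator gene Ciita was 3.01-fold lower. The list of p53 targets and senescence factors had a median of -0.62, with the cell cycle inhibitor gene Cdkn2b 4.73-fold lower. Matrix genes had a median of -0.62, with Col1a1 5.85-fold and Timp1 3.66-fold lower, and neutrophil markers had a median of -0.67.

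Oncofetal genes had a median of -1.23, with the trypsin inhibitor gene Spink1 9.96-fold, Akr1c18 7.19-fold and Igf2 3.63-fold lower. Pancreatic acinar genes had a median of -3.41, with Ctrb1 85.0-fold lower and Prss2 at least 109-fold lower; members of the trypsinogen family are near-identical and were not told apart here. Cfd, which encodes adipsin, was 13.9-fold lower. Immediate-early genes had a median of -0.70, with Egr1 4.00-fold lower.

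On the higher side, amino acid catabolism had a median of 0.43 (0.19 after quantile normalization), with serine dehydratase (Sds) at 0.86 and Mat1a at 0.82. The circadian list had a median of 0.34 (0.18 after cyclic loess), with Ciart 3.06-fold and Per3 2.29-fold higher. Gluconeogenesis had a median of 0.40 (0.08 after quantile normalization), against 0.25 for random lists as bright. In it, Ppargc1a was 2.45-fold higher, with Pck1 at 0.51 and G6pc at 0.03. After normexp correction the list was within its random lists (percentile 43.1). Bile acid synthesis had a median of 0.34, with Cyp8b1 2.89-fold and Cyp7a1 2.15-fold higher and the transporter gene Slc10a2 5.91-fold lower; it was within its random lists after cyclic loess (median 0.06, percentile 96.3) and after normexp correction (median 0.19, percentile 82.4). Lepr was 8.67-fold higher, with its other probe at 2.72, and the glycogen-targeting subunit gene Ppp1r3g was 9.76-fold higher. Differences were -0.04 for Srebf1, 0.29 for Cpt1a, 0.85 for Irs2, 0.52 for Igfbp1 and -0.16 for Cyp4a14. With outlier spots kept, Scd1 differed by -3.24 and Fasn by -0.41. The antioxidant list stood below its random lists with a median within 0.01 of 0, against -0.18 after quantile normalization, and was within them with outlier spots kept (percentile 8.84).

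Of the 2065 genes at least 2-fold higher or lower in aging diabetic than natural aging, 627 (30.4%, 95% Wilson interval 28.4% to 32.4%) were at least 2-fold different in the opposite direction on the metformin array and 670 (32.4%, 30.5% to 34.5%) on the APS plus metformin array. These intervals cover counting error only. Both comparisons share the aging diabetic array, so opposite directions arise by chance. When the 4 arrays were shuffled within each gene 100 times, the share averaged 40.1% for metformin (37.8% to 42.7%) and 40.1% for the combination (36.7% to 42.4%), so both observed shares lay below what exchangeable arrays give. Of the 1185 genes that were higher in aging diabetic, 266 were turned back with metformin and 477 with the combination. Of the 880 that were lower, 361 and 193 were. The shuffles were not split by direction, so these counts have no such level beside them. Of all genes past 2-fold against aging diabetic, 77.1% were higher with metformin and 38.8% with the combination. Hamp, higher in the aging diabetic array, was higher still by 1.37 log2 on the metformin array and 1.83 on the APS plus metformin array.

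Across 12689 genes well above background on all 4 arrays, the difference of aging diabetic from natural aging correlated with that of APS plus metformin from metformin at r = -0.0445. This was just outside the range of -0.0385 to 0.0356 over the shuffles. Each gene was shuffled separately, which breaks variation that genes share, so the range may be too narrow. After quantile normalization r was -0.0242, for which no shuffles were run. These differences share no array, and genes are not independent replicates. The differences of both treatments from the aging diabetic array correlated at 0.471 (shuffled mean 0.498), with a covariance of 0.195 (shuffled mean 0.240). Both treatments shared 327 genes that were higher (independent lists 63.9, shuffled mean 348.9) and 351 that were lower (independent lists 38.5, shuffled mean 565.7). Independent lists are counted over the 14485 genes tested in both comparisons. The single aging diabetic array could not be split to remove its part in this overlap.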

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

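The tests of a lower share of hepatocytes and of growth hormone genes were chosen only after the results were seen. Probes that matched no gene symbol enter none of the comparisons by gene. Among 9757 such probes detected in aging diabetic or natural aging, 772 were at least 2-fold higher in aging diabetic and 739 lower. Among the 14453 genes compared, 1185 were higher and 880 lower. What the unmatched probes stand for was not examined.

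Pancreatic acinar genes were high in the natural aging array, with a median against it of -4.10 log2 in the aging diabetic and -6.71 in the APS plus metformin array. The check by other probes gave no decision on an error of single spots. Only 1 other probe of these genes was detected (1 of 1 with the same 2-fold difference, 100%). As the source of the whole pattern, independent spot errors are argued against. In aging diabetic against natural aging, 14 of 15 members were at least 2-fold lower and 0 higher. Random lists as bright, which hold spot errors too, had a median of 0.004 with an SD of 0.19. The list was picked out for this difference, and an error in any 1 gene stays open. Pancreatic tissue or its RNA in the liver sample is a candidate explanation. Islet genes tested it, and only 2 of 8 were detected on both arrays, with a median of -0.19 for natural aging minus APS plus metformin (Ins1 -0.61, Ins2 0.24), so this cannot be told apart from expression in the liver: islets are a small part of the pancreas and the other islet genes were not well above background on these arrays. A difference between the groups themselves was not tested, since each has 1 array.

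Oncofetal, cell cycle and lymphocyte genes were high in the metformin array. An overall brightness or intensity trend of the array is argued against, since the lower of the medians after quantile normalization and cyclic loess was 100.4% of the original (1.32 log2). The check by other probes gave no decision on an error of single spots. Of 12 other probes 9 (75%) showed the same 2-fold difference, short of the 80% asked. As the source of the whole pattern, independent spot errors are argued against. At least 2-fold higher were 9 of 13 oncofetal, 14 of 24 cell cycle and 13 of 20 lymphocyte members, with 0 lower. Of all 15562 genes compared, 1851 were higher. The lists were picked out for this difference, and an error in any 1 gene stays open. A lower share of hepatocytes may raise markers of all other cell types alike; medians ran from 0.30 (cholangiocyte) to 1.42 (lymphocyte), and 9.28% of 10000 shuffles of members over these 6 lists gave a gap as large, so it stays open, as does an effect of metformin or of the animal. A first rule for this test, a gap over 2 bootstrap standard errors, was dropped because the pair of lists is picked as the extremes of 6; by that rule the gap of 2.71 standard errors would have argued against a lower share of hepatocytes, and macrophage markers went both ways (5 higher, 2 lower).

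Female-biased genes were high and male-biased genes low in the aging diabetic array. A female animal behind the aging diabetic array is argued against. The median of the 2 detected of 4 Y-linked genes differed by -0.13 log2 from natural aging (Eif2s3y -0.50, Uty 0.25). Eif2s3y was bright on both arrays (levels of 1.26 and 1.76), Uty was dim (-3.84 and -4.09), and Xist was well above background on neither. Xist was well above background on the 2 treated arrays, as were Eif2s3y and Uty. What this Xist signal comes from was not tested. The check by other probes gave no decision on an error of single spots. Only 3 other probes were detected (3 of 3 with the same difference, 100%). As the source of the whole pattern, independent spot errors are argued against. List medians were 1.28 (female-biased) and -0.85 log2 (male-biased). Random lists as bright, which hold spot errors too, had medians of -0.10 and -0.18 with SDs of 0.14 and 0.10. In each list 1 member went the other way, the lists were picked out for this difference, and an error in any 1 gene stays open. Weaker growth hormone signalling is a candidate explanation for the low male-biased genes, since growth hormone maintains male-biased expression. Whether it could raise female-biased genes was not tested. The median of 4 detected genes (Igf1 -0.36, Igfals -1.39, Cish -3.72, Ghr -0.77) was -1.08 log2. It was -1.39 over 5 genes with outlier spots kept, which adds Socs2 (-2.26). The median was -0.92 after quantile normalization and -0.95 after cyclic loess, short of the 1 log2 asked of every setting. Igf1 was then at -0.03 and -0.10 and Ghr at -0.48 and -0.54, so the Igf1 difference depended on the scaling. Igfals (-1.35 and -1.37) and Cish (-3.66 and -3.71) changed little. Diabetes and the animal itself stay open as untested explanations.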

How the results depend on the processing

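Keeping outlier spots was chosen as an alternative only after the data had been seen; the other 8 alternatives were set before. No paired analysis was possible because each group has 1 array and no number pairs the animals. Signal over background limits the dim genes: 12878 of the 14453 genes compared between aging diabetic and natural aging were well above background on both arrays, and the others give bounds. Of 135 recomputed counts, shares and correlations, 118 stayed and 17 moved. Staying means within 1.5 times the count, or within the interval or error of the share or correlation. Only the correlation could be counted as reversed, and it kept its sign in every alternative. Of 4033 recomputed differences of named genes, 0 reversed and 428 moved beyond measurement error. A change of sign was counted as reversed only where the original difference was at least 1 log2 in size. Of 1544 recomputed list medians 1125 stayed, 393 moved and 26 reversed, where only lists that stood apart could count as reversed. A list median stayed if it moved by no more than the SD of its random lists. The total hides a split between alternatives. Those that stayed were 76 of 172 after quantile normalization, 73 of 172 after cyclic loess and 77 of 172 in the series values. Centring on the median, which shifts each array by a constant, left 172 of 172 the same. Lists on the same side of their random lists under all 9 alternatives were 20 of 24 for aging diabetic against natural aging, 21 of 24 for metformin and 16 of 22 for APS plus metformin against aging diabetic, and 14 of 17 for APS plus metformin against metformin.

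Without a detection filter, more dim genes count: 2132 higher and 1363 lower in aging diabetic than natural aging, 3076 higher with metformin and 1107 higher and 1536 lower with APS plus metformin than in aging diabetic, and 631 higher and 3161 lower with APS plus metformin than with metformin; the correlation of the differences that share no array was -0.0907. Over genes detected on all arrays, which are fewer by construction, 1049 were higher with metformin than in aging diabetic, 242 higher and 1117 lower with APS plus metformin than with metformin, and 30.4% were turned back with APS plus metformin. After normexp the shares turned back were 27.9% with metformin and 29.4% with APS plus metformin. The correlation was -0.0242 after quantile normalization, -0.0154 after cyclic loess and -0.0242 in the authors' series values. Shuffles were not run under these alternatives, so no range stands beside these values. The series values were close to a quantile normalization, so they add little to it. The cause of these shifts was not tested.

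Medians reversed for these lists. In aging diabetic against natural aging, values follow for quantile normalization, cyclic loess and the series values. Fatty acid oxidation and PPAR-alpha targets were at 0.22, 0.16 and 0.19 and oxidative phosphorylation at 0.11, 0.056 and 0.091. Amino acid catabolism was at 0.27, 0.25 and 0.26 (0.020 after normexp). In metformin against aging diabetic, in that order, xenobiotic metabolism was 0.15, 0.14 and 0.17 (0.011 after normexp and 0.014 with averaged probes), and pericentral genes 0.15, 0.15 and 0.17. There, glycogen metabolism was -0.13 with averaged probes and -0.13 over genes detected on all arrays, where the antioxidant list was -0.024. In APS plus metformin against aging diabetic, amino acid catabolism was -0.0078 after quantile normalization. In APS plus metformin against metformin, the antioxidant list was -0.18, -0.20 and -0.17, and -0.045 after normexp. The cause of these reversals was not tested.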

Other observations

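Compared directly with natural aging, the treated arrays were closer to it than the aging diabetic array in some lists and further in others. Closer were immediate-early genes, with a median of 0.30 log2 with metformin and -0.27 with APS plus metformin against -1.03 in the aging diabetic array, matrix genes (0.44 and -0.18 against -0.66) and endothelial markers (-0.12 and 0.01 against -0.41, though both treated medians change sign after cyclic loess, to 0.028 and -0.047). Cholesterol synthesis was at 0.19 and 0.17 against -0.45, but after quantile normalization the metformin array was further from natural aging (0.53 against -0.34). Further were female-biased genes (3.66 and 2.498 against 1.28; 1.55, 1.25 and 0.83 without members that give only a bound), male-biased genes (-1.21 and -1.29 against -0.85) and heat shock genes (-0.94 and -0.90 against -0.34; after quantile normalization -0.50 and -0.72 against -0.06, so the order of the treatments turns). Sult2a2 was higher by at least 7.28 log2 with metformin and at least 7.61 with the combination, and Hamp by 5.71 and 6.17. Some lists parted the treatments. Pancreatic acinar genes were at -2.15 with metformin and -6.71 with the combination, against -4.10. Oncofetal genes were at 3.02 with metformin and 1.09 with the combination, the latter 0.48 without bounds, against 1.05 (0.96 without bounds) in aging diabetic. Neutrophil markers had a median of -1.42 with APS plus metformin, with 8 of 14 at least 2-fold lower. Against natural aging, 2021 genes were at least 2-fold higher and 732 lower with metformin, and 898 higher and 977 lower with APS plus metformin (1185 and 880 in aging diabetic).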
